A study of Homo sapiens with 6 samples.

How the data were processed

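Total RNA of 6 cultures was extracted with Trizol and labelled with biotin during reverse transcription from random hexamers, per the labels' protocols, and each sample was hybridised to a 1-channel array of non-coding RNA probes. The cultures were mammosphere-derived epithelial cells of 3 donors, 1 preexposed to DES and 1 to DMSO per donor, for 3 weeks. The donor of each culture was taken from the labels, and donors are numbered 1 to 3 here. Donors are separate biological samples, and the table holds 1 array per culture.

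The deposited table held 1 value per probe and array for 875 probes, all of them named as human, and the values are linear array intensity. Per the values in the deposited table, each array had a lowest intensity (0.659 to 1.05) shared by 49 to 159 probes. The square of value over floor was a whole number, within 0.01, for 97.2% to 98.4% of the values for which it was under 2000. This is what the geometric mean of 2 whole-number spot signals, floored at 1 and multiplied by 1 factor per array, would give. How that factor was chosen, the background correction, the treatment of spot flags and any filter applied by the authors are not given in the sources used here. Values at the floor have no order and only bound a level. Array medians of the tested probes lay between 4.90 and 5.24 on the log2 scale, so no further scaling was applied. The 75th percentile of intensity was lower on the DES than on the DMSO array of each donor (167, 163 and 157 against 215, 178 and 177).

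The log2 of each value was taken without a pseudocount. The 4 probes at the floor on all 6 arrays were left out, which left 871 probes of 417 microRNAs: 539 with names ending in A, 326 ending in P and 6 others. On this kind of array A is read as the mature and P as the precursor sequence, which the table does not spell out, and a mature probe can also bind its precursor. Probe names are those of the array's design, and no genome build is named, so no coordinates are given. Where a probe sat at the floor on all arrays of 1 group and on none of the other, the brighter group's mean was set against the lowest value above the floor on each array of the dimmer group, and the fold is given as a lower bound. A probe at the floor on part of a group's arrays kept its floor values in the fit, so its change and SE depend on the floor.

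DES was compared with DMSO in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a constant prior, two-sided), with donor as a fixed block and Benjamini-Hochberg adjustment over the probes tested. The fit had 2 residual degrees of freedom per probe and a prior worth 3.27, and the median SE of a log2 change was 0.71. Donor terms were tested with an F test in the same fit. The 19 microRNA lists were tested on 1 value per microRNA, the mean of its probes, with fry (directional and mixed) and camera (preset correlation 0.01 and estimated correlation), adjusted over the lists. Fry and camera ask different questions: fry whether a list moves at all, camera whether it moves relative to other microRNAs.

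Groups, lists, the tests of the report, the alternatives and the rule for named probes were fixed before the data were examined, apart from 2 alternatives added later (a common floor of 32, and A probes alone). Further tests chosen after the results were seen are named as such with the other observations. The rule took every miR-9 probe, the 15 largest changes each way past the adjusted threshold (none passed), the 12 probes each way with the smallest unadjusted p among those moving the same way in all 3 donors, and up to 4 members of each list with the smallest unadjusted p. A probe named outside this rule is said to have been chosen after its values were seen.

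Pairing comes from the donors named in the labels. The deviations from the group means of the cultures of a donor correlated at -0.021, -0.017 and 0.18, so donors explained little of the spread. In 20 simulations of 871 probes with the fitted spread, 200 of them changed, the DES versus DMSO test called 0.373% of 2-fold, 2.76% of 4-fold and 42.2% of 16-fold changes at an adjusted p of 0.05, and 14.3%, 59.5% and 93.3% at an unadjusted p under 0.05. Unchanged probes passed the unadjusted threshold in 5.32%. The simulated spread did not follow signal level, whereas the real median SE was 0.61 in the brightest level quartile and 0.84 in the dimmest. These rates therefore do not describe bright or dim probes separately. A 2-fold shift of the miR-17-92 list was called in 100% of simulations by camera with the preset correlation, 5% by fry and 0% by camera with an estimated correlation. The simulated noise was independent between probes, whereas the real list had an estimated correlation of 0.24. The simulations therefore cannot show how often camera with the preset correlation calls such a list falsely in these data.

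The alternatives were no donor block, donor as a random block, quantile normalization, median centring, cyclic loess, no filter, dim probes left out, 1 value per microRNA, an intensity trend or a robust prior in eBayes, log2 of value plus 16, leaving out each donor, a 2-fold limit, an adjusted p of 0.1, and the 2 added ones. No scanner files, array positions or hybridisation batches were analysed here.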

Results

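Small non-coding RNA was profiled in mammosphere-derived epithelial cells, which are grown from human breast tissue as floating spheres enriched in progenitor cells and then allowed to differentiate. The tissue came from reduction mammoplasties of 3 donors. Each donor gave 1 culture that had been exposed for 3 weeks to diethylstilbestrol (DES), a synthetic estrogen, and 1 culture exposed to the vehicle DMSO, so 6 arrays formed 3 pairs. The table held 875 human probes per array in units of linear intensity. Median intensity per array lay between 29.6 and 37.7. The brightest probe lay between 42903 and 46205 on the DES arrays and between 51114 and 60307 on the DMSO arrays. From 49 to 159 probes per array sat at that array's lowest value, and the precision of every comparison was limited by the 3 arrays per group.

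The series title asks whether a xenoestrogen represses microRNA genes in breast epithelial cells, and DES cultures were compared with DMSO cultures of the same donor for that question. Among the probes that moved the same way in all 3 donors, the lower ones with the smallest p-values included several of the miR-17 and miR-16 families, along with miR-146b, which dampens NF-kB signalling, and miR-454-3p. The miR-146b probe was lower by a log2 change of -2.48 (SE 0.67, n = 3 pairs), from a geometric mean intensity of 285 to 51.2, and miR-454-3p by -2.21 (SE 0.60), from 296 to 63.9. The miR-337 probe sat at the floor on all 3 DES arrays and on the geometric mean was at least 17.4-fold lower than under DMSO. It was dim under DMSO as well, at intensities of 37.3, 3.32 and 39.1 in donors 1 to 3, so the bound does not hold for each donor. On the higher side, the miR-659 precursor probe went from a geometric mean of 60.3 to 501 (log2 change 3.05, SE 0.58), miR-668 from 12.3 to 112 (3.19, SE 0.67) and miR-326 from 21.8 to 122 (2.49, SE 0.65).

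None of these differences passed the adjusted threshold. In the limma fit with donor as a block, 0 of 871 tested probes passed a Benjamini-Hochberg adjusted p of 0.05, and the lowest adjusted p was 0.581. At an unadjusted p under 0.05 there were 71 probes (8.15%), 39 higher and 32 lower, where 43.55 would be expected by chance. The balance depended on the donors, with 62 higher and 19 lower without donor 1, and 33 higher and 42 lower without donor 3. Of the 71, 68 moved the same way in all 3 donors. A small p in a paired fit itself favours a shared direction, so this count is no separate support. A variance prior that follows intensity took each probe's variance from its intensity alone and called 30 probes, 3 higher and 27 lower, of which 21 were among the 71. Those 30 included probes of miR-17-5p, miR-16, miR-93, miR-106a, miR-146b, miR-659 and miR-668, and no other alternative called any probe at 0.05.

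The remaining probes named by the same rule were mostly dim. Lower after DES were the precursor probes of miR-511-1 (log2 change -2.26, SE 0.67) and miR-140 (-2.36, SE 0.73), and the probes of miR-299-3p (-3.82, SE 1.14), miR-656 (-2.72, SE 0.90) and miR-143 (-3.32, SE 1.02). Higher after DES were miR-345 (3.44, SE 0.57), miR-409-5p (2.92, SE 0.65), miR-493-3p (3.58, SE 0.95), miR-624 (2.13, SE 0.59) and the probe shared by miR-518a-5p and miR-527 (2.68, SE 0.59). The precursor probes of miR-181d (3.30, SE 0.72), miR-194-2 (3.54, SE 0.84), miR-346 (4.14, SE 1.09) and miR-370 (2.76, SE 0.75) were also higher. Each had an adjusted p of 0.581. The miR-656 and miR-143 probes sat at the floor on 2 of the 3 DES arrays, the miR-493-3p, miR-624, miR-181d and shared miR-518a-5p and miR-527 probes on 2 of the 3 DMSO arrays, and miR-409-5p, miR-194-2 and miR-346 on 1 DMSO array, so their changes and errors depend on the floor. The same holds for further probes named below: the precursors of miR-18b and miR-107 (floor on 2 DMSO arrays), those of miR-183, miR-26a-1 and miR-520g and the probes of miR-199a*-3p, miR-223, miR-124a3 and miR-518b (1 DMSO array), and miR-190 and miR-451 (1 DES array).

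The direction of the differences followed signal level. Among the 435 probes above the median level, which corresponds to an intensity of 25.8, 5 probes were higher and 19 lower at an unadjusted p under 0.05, whereas the 436 dimmer probes gave 34 higher and 13 lower. Probes with names ending in A, read here as the mature sequence, gave 18 higher and 27 lower, and those ending in P, read as the precursor, 21 higher and 5 lower. Across all tested probes 46.2% were lower after DES, with a median log2 change of 0.094. Both values turned without donor 3 (54.1% and -0.12) and with dim probes left out (57.0% and -0.11). Quantile normalization gave 25 higher and 40 lower probes at an unadjusted p under 0.05, and cyclic loess 27 and 43.

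**Figure D1:**
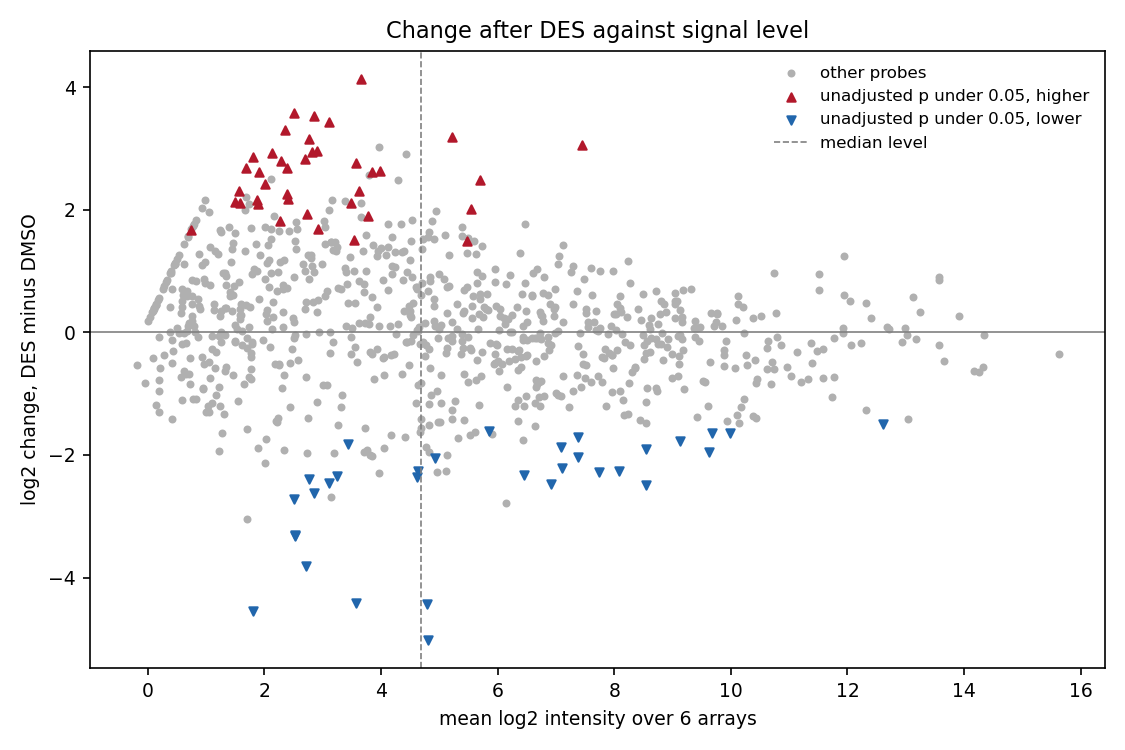
Log2 change after DES (y axis, DES minus DMSO, fit over 3 donors) against mean log2 intensity over the 6 arrays (x axis) for the 871 tested probes. Triangles mark the 39 higher and 32 lower probes at an unadjusted p under 0.05; the higher ones lie mostly left of the dashed median level, with 34 of the 39 in the dimmer set.

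The miR-17-92 cluster and its paralogs, growth-promoting clusters activated by MYC, had a list median below 0 in each donor. Of its 19 mature probes, 12 were lower in all 3 donors. The miR-17-5p probe had a mean log2 intensity of 10.60 ± 0.18 (SD, n = 3) under DMSO and 8.65 ± 0.45 under DES, a log2 change of -1.95 (SE 0.60, 95% interval -3.46 to -0.43), with changes of -1.61, -2.59 and -1.64 in the 3 donors. The probes of miR-93 and miR-106a were lower by -2.04 (SE 0.59) and -1.77 (SE 0.60). The dim precursor probe of miR-18b went the other way (2.86, SE 0.83), and 3 of all 24 probes of the list were higher in all 3 donors. The median log2 change was -0.80 over the list's 14 measured microRNAs and -1.36 over its mature probes.

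Against all other microRNAs the miR-17-92 list was lower by camera with a preset correlation of 0.01 (adjusted p = 0.0277 over 19 lists), and this call was lost with an estimated correlation (adjusted p = 0.914). By fry, which tests whether the list moves one way on balance, the adjusted p was 0.902. With simulated independent noise, a 2-fold shift of this list was called in 0% by camera with estimated correlation and 5% by fry. These tests therefore cannot show that the list did not move. No member passed when adjusted over all probes or adjusted over the list alone. Without donor 3 the camera value was 0.289, without donor 2 it was 0.0807, and under cyclic loess it was 0.0541.

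Mature probes of the miR-15/16 family, which restrains the cell cycle and targets BCL2, were mostly lower in the same cultures, while the family as a list was not lower in each donor. Of its 10 mature probes 7 were lower at an unadjusted p under 0.05 and in all 3 donors. Of its 7 precursor probes 1 was higher at an unadjusted p under 0.05, and 3 of all 17 probes were higher in all 3 donors. The miR-16-2 probe was lower by -2.48 (SE 0.80), miR-16-1 by -2.27 (SE 0.75), miR-16a-chr13 by -2.27 (SE 0.63) and miR-16b-chr3 by -1.91 (SE 0.65). These 4 probes are named for loci that yield the same mature miR-16, so their values are not independent of each other. Over the 7 microRNAs, with precursor probes included, the median log2 change was -0.91, with donor medians of -1.82, -0.39 and 0.12, and over the mature probes it was -1.89. The list did not pass by camera (adjusted p = 0.204) or fry (adjusted p = 0.933), and the lowest p adjusted over the list alone was 0.0956.

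**Figure D2:**
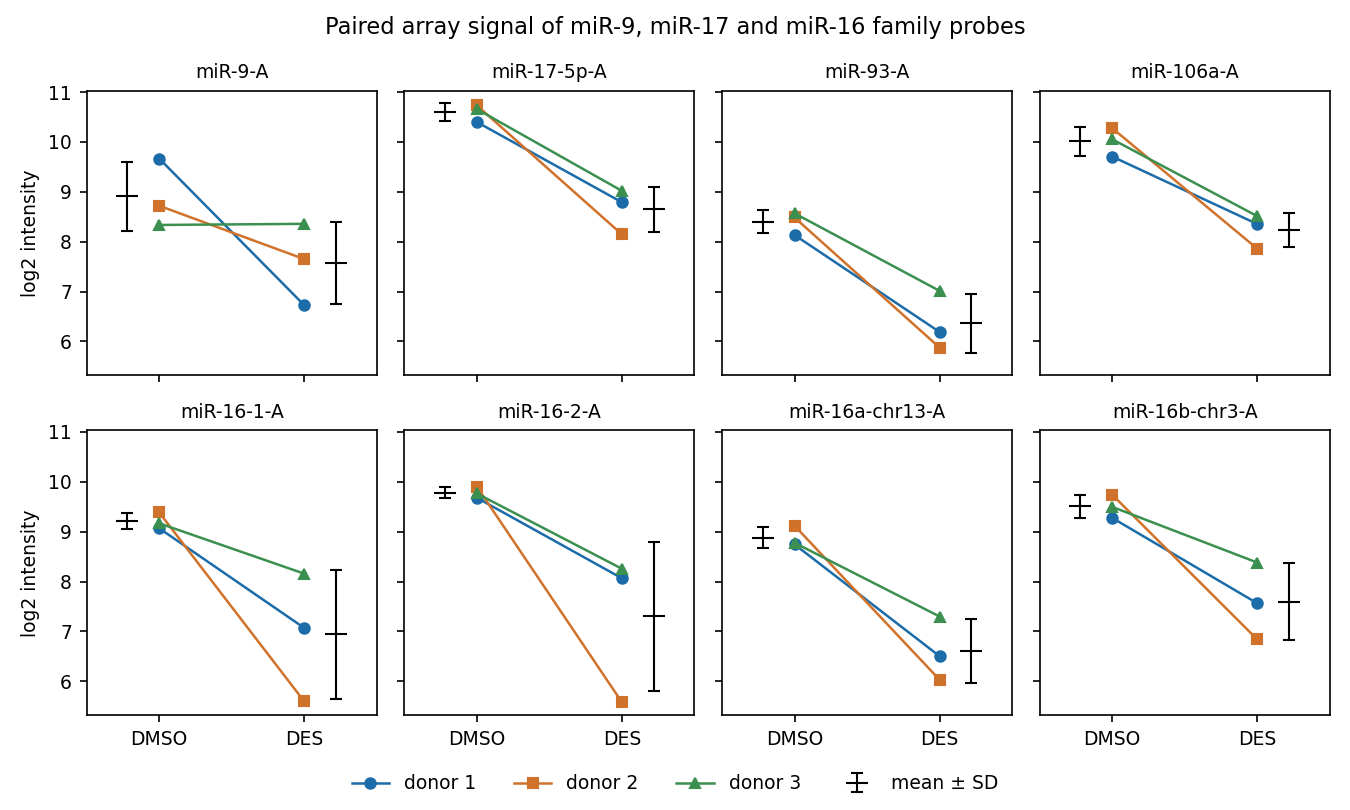
Log2 intensity (y axis) of 8 mature probes under DMSO and DES (x axis), with 1 line per donor and the mean ± SD over 3 donors in black. The miR-17-5p, miR-93, miR-106a and miR-16 probes are lower after DES in each of the 3 donors, while the miR-9 probe is lower in donors 1 and 2 and level in donor 3.

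The miR-9 family, whose genes can be silenced by promoter methylation in breast tumours, was measured by 4 probes. The miR-9 probe was lower by a log2 change of -1.33 (SE 0.78, adjusted p = 0.638), from a mean log2 intensity of 8.91 ± 0.69 (SD, n = 3) to 7.58 ± 0.82. Its change was -2.94 in donor 1, -1.07 in donor 2 and 0.022 in donor 3, and it was -0.52 without donor 1. The other 3 probes differed by less than their error, with 0.33 (SE 0.70) for miR-9-5p, -0.15 (SE 0.59) for miR-9* and -0.27 (SE 0.88) for miR-9*-3p. The miR-9-5p probe changed by 1.62, -0.021 and -0.62 in donors 1 to 3, so it rose in donor 1, where the miR-9 probe fell most. As the star strand is named 3p here, miR-9 and miR-9-5p are names of the same mature strand. Their probes are thus not independent of each other and did not agree. The median over the family was -0.36 (fry adjusted p = 0.933). Separate miR-9 loci were not analysed here.

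In the wider list of 13 microRNA genes described as methylated in breast cancer, 0 of 29 probes passed at an unadjusted p under 0.05, and the median log2 change was 0.10 (fry adjusted p = 0.933; -0.020 with a common floor). The probe of miR-125b2, a microRNA often low in breast tumours, was lower (-1.22, SE 0.64). Dimmer probes of miR-203 (precursor, 1.30, SE 0.67), miR-152 (precursor, 1.09, SE 0.60) and miR-124a3 (1.82, SE 1.01) were higher. The miR-29 family, which targets DNA methyltransferases, had a median of -0.020, and it was above 0 under quantile normalization, cyclic loess and with dim probes left out. Its values ran from -1.15 (SE 0.67) for the miR-29b-1 precursor through -0.11 (SE 0.61) for miR-29b2 and 0.085 (SE 0.59) for the miR-29a precursor to 0.19 (SE 0.63) for the mature miR-29b-1 probe.

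MicroRNAs linked to estrogen or its receptor had no common direction. Over 14 microRNAs the median log2 change was 0.040 and the mean -0.071 (fry adjusted p = 0.933), and mature probes alone had a median of -0.45. The median was also below 0 with dim probes left out, with 16 added and with a common floor. The miR-190 probe was lower (-2.34, SE 0.89), as was miR-26a, which targets EZH2 (-1.39, SE 0.69, from a geometric mean of 2230 to 851). The precursor probes of miR-222, a regulator of ESR1 (1.77, SE 0.73), and of miR-26a-1 (3.02, SE 1.39) were higher.

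The primate-specific placental cluster of imprinted microRNAs had a median log2 change of 0.74 over 35 microRNAs, with donor medians of 0.032, 0.24 and 1.30. It passed camera with the preset correlation (adjusted p = 0.0334), but not with an estimated correlation (adjusted p = 0.914) or by fry (adjusted p = 0.933). Besides the miR-518a-5p and miR-527 probe, miR-518b (2.16, SE 0.63), the miR-520g precursor (2.83, SE 0.88) and miR-526b-5p (2.31, SE 0.85) were higher, at geometric means of 1.73, 2.44 and 5.52 under DMSO, close to the floor. The preset value was 0.175 under quantile normalization, 0.729 under cyclic loess, 0.343 with dim probes left out, 0.0655 with 16 added, 0.256 with a common floor, 0.260 for mature probes, 0.0662 without donor 2 and 0.369 without donor 3.

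Imprinted microRNAs of the DLK1-DIO3 cluster went both ways. Of its 82 probes 6 were higher and 4 lower at an unadjusted p under 0.05, among them miR-668, miR-409-5p and miR-493-3p on the higher side and miR-337 on the lower. The median over 40 microRNAs was 0.039, with a median below 0 under quantile normalization and cyclic loess, and the mixed fry test, which counts changes in either direction, had its lowest adjusted p here (0.170). The embryonic stem cell clusters had a median of 0.20 (fry adjusted p = 0.933; -0.070 with dim probes left out), with miR-302b-3p at 1.63 (SE 0.74), miR-372 at 1.08 (SE 0.64) and the miR-371 precursor at -1.15 (SE 0.58). The miR-302a-3p probe sat at the floor on all 3 DMSO arrays and on the DES array of donor 3, with intensities of 3.66 and 1.98 in the DES cultures of donors 1 and 2, so no fold is given.

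The epithelial list did not pass in either direction. The miR-205 probe, a marker of basal breast epithelium, had geometric means of 24439 under DMSO and 15585 under DES (log2 change -0.65, SE 0.68). The miR-200 family, which represses ZEB1 and ZEB2, had with miR-205 a median of -0.39 over 6 microRNAs (fry adjusted p = 0.933), with -0.91 (SE 0.73) for miR-200b, -1.21 (SE 0.89) for miR-200a-3p and 1.21 (SE 0.59) for the dim miR-200a*-5p. The miR-183 cluster, low in breast progenitors, had a median of 0.92 over 3 microRNAs (fry adjusted p = 0.902), which turned to -0.47 with dim probes left out and to -0.068 with a common floor. Its members ranged from -0.81 (SE 0.85) for miR-182-5p to 2.68 (SE 0.91) for miR-182*-3p, with miR-183 at 0.99 (SE 1.04) and its precursor at 0.85 (SE 0.89). The let-7 list was represented by miR-98 alone (0.16, SE 0.68), which was below 0 under quantile normalization and cyclic loess; let-7 itself was not analysed here.

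The HOX-embedded microRNAs had a median of -0.21 over 5 microRNAs (fry adjusted p = 0.902) and of -1.01 over 8 mature probes. The probes of miR-196a-2, miR-196a2 and miR-196a1 were lower by -1.42 (SE 0.62), -1.34 (SE 0.63) and -1.21 (SE 0.68), and miR-10b by -1.63 (SE 0.78). Each of these 4 was lower in all 3 donors. The brightest mature miR-196a probe, miR-196a-1, chosen after its values were seen, went the other way in all 3 donors (0.31, SE 0.57). The miR-196a probes are named for loci that yield the same mature sequence, so they are not independent of each other and did not agree. The p53-linked list had a median of 0.087 (fry adjusted p = 0.933), and it was -0.060 under cyclic loess, -0.52 with dim probes left out, -0.14 with a common floor and -0.36 for mature probes. Within it the mature miR-34a probe was at -0.83 (SE 0.60), the miR-107 precursor at 2.80 (SE 0.85) and the miR-194-1No2 probe at 0.86 (SE 0.68).

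The widely expressed miR-23/24/27 clusters and the miR-30 family had medians of -0.089 and -0.095 (fry adjusted p = 0.933 for each), which were above 0 under quantile normalization and cyclic loess. With a donor left out they ran from -0.88 to 0.60 and from -0.70 to 0.27. The bright miR-23a and miR-23b probes had log2 changes of -0.63 (SE 0.60) and -0.57 (SE 0.64), miR-24-2 of -0.18 (SE 0.71) and the dim miR-24-5p probe of 0.35 (SE 0.96). In the miR-30 family miR-30b was at -0.82 (SE 0.75), miR-30c-1 at -0.92 (SE 0.76), the miR-30c-2 precursor at -1.02 (SE 0.61) and the miR-30d precursor at 1.25 (SE 0.98).

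Markers of other cell types that such cultures may hold were also compared. The stromal and smooth muscle list had a median of -0.66 over 5 microRNAs (camera adjusted p = 0.0603; fry adjusted p = 0.933). Its donor medians were 0.59, -0.47 and -3.05, and without donor 3 the median was 0.084. The miR-143 probe, at the floor on 2 DES arrays, and the miR-199b probe were lower in all 3 donors (-3.32, SE 1.02, and -2.05, SE 0.72). The miR-214 probe (-0.96, SE 0.88) changed by 0.59, -0.43 and -3.05 in donors 1 to 3. The miR-199a*-3p probe (-1.89, SE 1.47) was lower in donor 3 only (0.45, 0.19 and -6.30). In donor 3, where the mature miR-17-92 and miR-15/16 probes together were lower by a median of -1.01, miR-214 went from an intensity of 1029 to 124.

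Blood and endothelial microRNAs had a median of 0.80 (fry adjusted p = 0.933; -0.28 without donor 3). The red cell microRNA miR-451 was lower (-2.69, SE 1.10), and the endothelial miR-126-3p (1.72, SE 0.76), the myeloid miR-223 (1.66, SE 0.76) and the lymphoid miR-150 (1.77, SE 0.93) were higher. Muscle, liver and neural microRNAs had a median of -0.47 (fry adjusted p = 0.933). This list was fixed to stand for tissues not expected in the culture, whose probes should be dim. As a set they were not dimmer than others, with a median log2 level of 4.79 against 4.69 over all tested probes. Of the 3 mature probes of the muscle microRNA miR-1, miR-1-2 and miR-1-1 were lower in all 3 donors (-5.02, SE 1.74, and -4.43, SE 1.63), and the probe named miR-1, chosen after its values were seen, was lower in 2 (-2.26, SE 1.24). The sizes for miR-1-2 and miR-1-1 depend on the floor, where both sat on the DES array of donor 1; in donor 3 miR-1-2 changed by -0.43. The precursor probe of the neural miR-128a was at 1.05 (SE 0.57), and the cardiac miR-208 probe sat at the floor on all 3 DMSO arrays and on the DES array of donor 1, with intensities of 2.80 and 19.1 in the DES cultures of donors 2 and 3, so no fold is given.

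**Figure D3:**
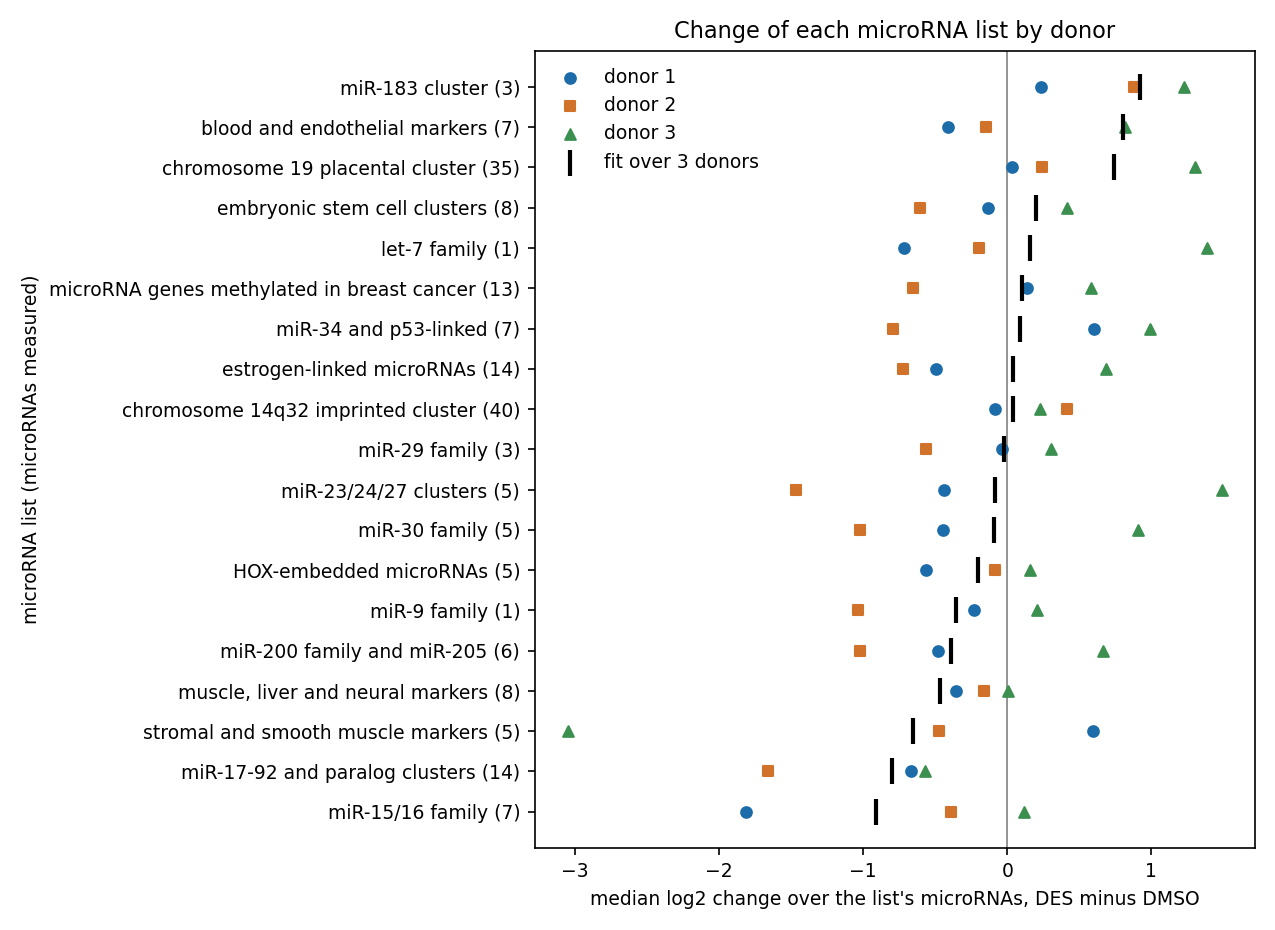
Median log2 change, DES minus DMSO (x axis), over the microRNAs of each of the 19 lists (y axis, with the number of microRNAs measured). Coloured symbols are the 3 donors and black ticks the fit over all 3. The miR-17-92 list is below 0 in each donor (-0.67, -1.66 and -0.57), and the stromal list lies at -3.05 in donor 3 against 0.59 and -0.47 in the others.

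The responses of the 3 donors had little in common over the whole table. Across the 871 probes, which are not independent replicates, the log2 changes of donors 1 and 2 correlated at r = 0.23, those of donors 1 and 3 at 0.062 and those of donors 2 and 3 at 0.082 (mean r = 0.12, mean Spearman rho = 0.15). Over the 435 brighter probes the same values were 0.46, 0.15 and 0.19. The median change was -0.13 in donor 1, -0.19 in donor 2 and 0.36 in donor 3. At least 1.5-fold changes the same way in all 3 donors were seen for 104 probes, 50 higher and 54 lower, against 48 to 72 when the sign of 1 donor was turned.

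Donors themselves differed no more clearly than exposures did. The limma F test of the donor terms called 0 probes at an adjusted p of 0.05 and 63 at an unadjusted p under 0.05. Log2 intensities of arrays correlated at 0.861 to 0.878 between the cultures of a donor and at 0.829 to 0.912 between donors at the same exposure.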

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

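The common floor of 32 and the fit on A probes alone were chosen after the data were seen; the other alternatives were planned. The count of 0 probes at an adjusted p of 0.05 was the same under every setting run except 1: an intensity trend in the variance prior called 30 probes (107 at an unadjusted p under 0.05, of which 73 were lower). The degrees of freedom of this prior, estimated from the data, were infinite, against 3.27 in the main fit, so each probe's variance came from its intensity alone. The SE was lower for the bright miR-17-5p probe (0.40 against 0.60). It was higher for miR-668 (0.88 against 0.67) and miR-337 (1.42 against 0.88), which were also called. For miR-668 and miR-337 a smaller SE thus cannot have given the call. For the other called probes, how far the SE and how far the degrees of freedom gave the calls was not tested. The lowest adjusted p was 0.0541 with dim probes left out, 0.429 without the donor block and 0.389 with donor as a random replicate block (correlation 0.0507). The paired and unpaired fits differed little: without the block 75 probes had an unadjusted p under 0.05 (37 higher, 38 lower) against 71 (39 and 32), and the miR-17-92 and placental lists also passed camera with the preset correlation (adjusted p = 0.00391 and 0.0460), while in the fit with the block neither passed with an estimated correlation (0.914 for each). The alternative with probes of other organisms was not run, as all probes are named as human. Lists already held 1 value per microRNA. List tests do not use the trend or robust prior, so these moved no list. No list passed fry in 285 alternative values (smallest adjusted p 0.173). For the values below the cause was not tested, except where fewer donors or probes entered by construction. Dim probes are limited by their small distance from the floor.

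Probes higher at an unadjusted p under 0.05 numbered 25 under quantile normalization, 21 with dim probes left out, 17 with the common floor, 20 for A probes and 33 to 62 with a donor left out. Lower ones numbered 50 with dim probes left out, 20 with 1 value per microRNA, 58 with 16 added and 19 to 42 with a donor left out. Changes of at least 1.5-fold in all donors numbered 50 with dim probes left out, 43 with 1 value per microRNA, 46 with 16 added, 50 at 2-fold, 40 with the common floor, 62 for A probes and 198 to 279 over any 2 donors, where fewer donors had to move alike. The share of lower probes was 57.0% with dim probes left out. Mean correlation between donors was 0.27 with dim probes left out, 0.24 with 16 added, 0.28 with the common floor and 0.062 to 0.23 with a donor left out. Donor terms called 1 probe with dim probes left out and 1 with the common floor.

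The camera value of the miR-17-92 list was 0.0541 under cyclic loess and 0.0152 to 0.289 with a donor left out. For the placental list it was 0.175 under quantile normalization, 0.729 under cyclic loess, 0.343 with dim probes left out, 0.0655 with 16 added, 0.256 with the common floor, 0.260 for A probes and 0.00886 to 0.369 with a donor left out.

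List medians changed sign as follows. Under quantile normalization let-7 was -0.24, DLK1-DIO3 -0.057, miR-29 0.19, miR-23/24/27 0.081 and miR-30 0.10. Under cyclic loess let-7 was -0.023, p53-linked -0.060, DLK1-DIO3 -0.067, miR-29 0.25, miR-23/24/27 0.078 and miR-30 0.071. With dim probes left out miR-183 was -0.47, estrogen-linked -0.30, p53-linked -0.52, embryonic -0.070 and miR-29 0.025. With 16 added let-7 was -0.0071 and estrogen-linked -0.032. With the common floor let-7 was -0.29, miR-183 -0.068, estrogen-linked -0.026, p53-linked -0.14 and methylated -0.020. For A probes estrogen-linked was -0.45 and p53-linked -0.36. With a donor left out the ranges were -0.0096 to 0.80 for p53-linked, -0.063 to 0.27 for methylated, -0.70 to 0.27 for miR-30, -0.35 to 0.14 for miR-29, -0.88 to 0.60 for miR-23/24/27, -0.45 to 0.59 for let-7, -1.74 to 0.084 for stromal, -0.28 to 1.27 for blood, -0.57 to 0.56 for estrogen-linked and -0.10 to 0.37 for embryonic.

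Of 86 named probes, 14 changed sign somewhere. The miR-98 probe was -0.24 under quantile normalization, -0.023 under cyclic loess, -0.0071 with 16 added and -0.29 with the common floor. Under quantile normalization miR-29b2 was 0.081 and miR-24-2 0.021, and under cyclic loess 0.17 and 0.078. With the common floor miR-9*-3p was 0.12, miR-9* 0.087 and the miR-183 precursor -0.16. With a donor left out the ranges were -0.32 to 0.80 for miR-9-5p, -1.11 to 0.77 for miR-9*-3p, -0.35 to 0.13 for miR-9*, -0.27 to 1.52 for the miR-183 precursor, -0.42 to 1.81 for miR-183, -1.74 to 0.038 for miR-182-5p, -0.41 to 0.23 for miR-29b2, -0.18 to 0.29 for the miR-29a precursor, -0.092 to 0.63 for miR-29b-1, -0.80 to 0.40 for miR-24-2, -0.91 to 1.07 for miR-24-5p, -0.45 to 0.59 for miR-98, -3.06 to 0.32 for miR-199a*-3p and -1.74 to 0.084 for miR-214. Past an adjusted p of 0.05, all with the intensity trend, were 17 named probes.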

Other observations

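The tests of the other miR-17-92 and miR-15/16 probes and of the dim probes without donor 3, over all and by level quartile, the placental medians by scaling, and the joining of the miR-17-92 and miR-15/16 lists, on which the comparison with level-matched probes rests, were chosen after the results were seen. The remaining tests were chosen before their own values were seen, although the low stromal median in donor 3 had been seen when its test was chosen.

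Probes outside the rule for named probes were picked out here after their values were seen. With an intensity trend, which took each probe's variance from its intensity alone, the miR-100 probe, bright in these cells, was lower by a log2 change of -1.49 (adjusted p = 0.0112), miR-206, a muscle microRNA that targets ESR1, by -1.37 (adjusted p = 0.0224) and miR-25 by -1.36 (adjusted p = 0.0243). The same fit called miR-15a (-2.33), miR-15b (-1.87) and miR-195 (-1.71) lower, and all 6 were lower in each donor. With the constant prior these probes did not pass, and of the 30 probes the trend called, 28 lay above the median level and 29 moved the same way in all 3 donors. Choosing probes by a large mean change over the donors favours such agreement, so it is no separate support.

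The lower signal of the mature probes of the miR-17-92 and miR-15/16 lists was weighed first. Over the 29 probes the median log2 change was -1.48 (-1.20, -1.79 and -1.01 in the 3 donors), and 19 were lower in every donor. Compression of bright signals on the DES arrays would lower level-matched probes alike, but 10000 level-matched sets had a middle value of -0.14 and a 5th percentile of -0.46, which argues against compression as the whole cause. The percentile of 0 itself overstates the contrast, since the lists were joined after their probes were seen to be lower and hold similar sequences, while the random sets hold unrelated probes. One shared signal of the near-identical miR-17, miR-20, miR-93 and miR-106 probes would leave the others near 0. The other 23 probes had a median of -1.34, but their parts differ. The 10 miR-15/16 probes, at a median of -1.89 and below 0 in each donor, were not near 0. They were joined after being seen to be lower, so this outcome was known beforehand and is no separate evidence against that signal. The other 13 miR-17-92 probes had a median of -0.33 (-0.71, -1.23 and -0.34 in the 3 donors), with 6 lower in every donor and 1 at an unadjusted p under 0.05, and others higher, so for the miR-17-92 list a shared signal stays open. Sequence similarity among the miR-15/16 probes, unequal labelling of short RNA, differences in growth between the cultures and a lower level of these microRNAs after DES also stay open.

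With 10 splits of the 6 arrays into 3 and 3, a share under 0.05 cannot be reached. The real split gave 71 probes at an unadjusted p under 0.05 and 2 lists by camera with the preset correlation. The other 3 splits that part all 3 pairs gave 32 to 40 probes and at most 1 list. The remaining 6 splits part only 1 donor's pair. With the donor block they form 3 couples of the same fit, each of which estimates that donor's own difference between DES and DMSO, so their values, at most 62 probes and 2 lists, hold the exposure and are no chance values.

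Dim probes were higher after DES, with a median log2 change of 0.41 over the 436 probes below the median level, and the placental list lies among them. Over donors 1 and 2 alone the dim median was 0.070, but the donors differed by level. In the dimmest level quartile the donor medians were -0.19, -0.41 and 1.46 and the value over donors 1 and 2 was -0.11. The donor 1 median is the ratio of the floors of its 2 arrays, which is also the change of miR-208, at the floor on both. It is thus no measured change, and the values there depend in part on the floor. A raised dim end on the DES array of donor 3 is no more than a candidate explanation there. In the next quartile, which held 23 of the 34 dim higher probes, donor 2 rose as donor 3 did (-0.14, 0.69 and 0.72), and over donors 1 and 2 the value was 0.34 against 0.52 over all 3, which leaves the explanation open. Fewer probes sat at the floor on the DES than on the DMSO array in donor 3 (49 against 159) and in donor 2 (88 against 141), and about as many in donor 1 (107 against 106). For the placental list the shift shared by dim probes stays open. Its median of 0.74 lay at percentile 99.7 of 10000 level-matched lists, with a 95th percentile of 0.62, but the excess is small against the SD of its donor medians (0.68), and the random lists hold unrelated microRNAs, whereas this list had an estimated correlation of 0.19. The median was 0.40 (SD of donor medians 0.11) under quantile normalization and 0.28 (SD 0.10) under cyclic loess, where the list no longer passed camera with the preset correlation (adjusted p = 0.175 and 0.729, against 0.0334). The cause of that loss was not tested. With dim probes left out the adjusted p was 0.343, and with an estimated correlation on the deposited values 0.914. Cross-hybridisation among its similar sequences was not tested.

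The stromal markers were lower after DES in donor 3, at a median log2 change of -3.05, percentile 0 of 10000 level-matched sets, against percentiles 85.4 and 49.97 in donors 1 and 2. The percentile of 0 overstates the contrast, since the list and donor were singled out after their median was seen to be low. The list also holds several probes of miR-199a, while the random sets hold unrelated probes. Fewer stromal cells in the DES culture of donor 3 might give the lower values, but the 5 probes above an intensity of 100 in its DMSO culture did not change alike, with a range of 5.12 on the log2 scale. The low end of that range was miR-199a*-3p alone (-6.30, from 177 to 2.24, near the floor), and the other bright probes lay between -3.05 and -1.19. The brightest of the 5 in that DMSO culture, miR-214 and miR-145, went from 1029 to 124 and from 989 to 435, although intensities of different probes do not rank RNA levels. Myoepithelial cells are known to express miR-143 and miR-145, 2 of the list's 5 microRNAs, so a shift of cell types and a change within cells cannot be told apart with 1 culture per exposure.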
